A study of Homo sapiens with 12 samples.

How the data were processed

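Transcripts were measured in REC1 cells, an established human mantle cell lymphoma line, after DMSO, ibrutinib, SPX5551 or the combination of ibrutinib and SPX5551, each at 4, 8 and 12 h, with 1 library per treatment and time and 12 libraries in all. Per the labels' protocols, total RNA was extracted, poly(A) RNA was selected with magnetic beads, libraries were made with a directional RNA kit, and sequencing was done on a NextSeq2000. The labels also give the molecule as genomic DNA and the library source as genomic, which the RNA protocol contradicts. The values were read as transcript counts, and ribosomal protein genes held 8.36 to 12.1% of them. Per the submitters' processing notes, BWA and the genome build hg38 were used. The version of BWA, the counting tool, the gene annotation and the strand setting used for counting are not given in the sources used here. Doses are not given there either.

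The authors deposited a table of counts per Ensembl gene with 60483 genes and 1 column per library, and a table of log2 CPM (counts per 1e6 counts of a library) for 14767 of these genes. Per the file headers, both tables name the columns by time, cell line and treatment. The deposited counts are whole numbers with no sign of normalization. The deposited log2 CPM values share 1 lowest value of -3.50 and correlated with log2 CPM recomputed from the counts at r of at least 0.999997 in each library; how the authors normalized and filtered them is not given. Total counts per library ranged from 19336303 to 28934030. PCR copies were not marked by molecular identifiers, so counts carry more than counting error. The closest pair of libraries differed by a chi-square of 4.70 per degree of freedom, where counting error alone gives about 1, so no library repeated another.

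Columns were given to treatments by the treatment and time in the column header, which match the sample titles and treatments. The free-text description of each sample names the column of another treatment, and this pairing was run as an alternative. All comparisons, tests, gene lists and alternatives were fixed before the data were examined, except those named as added below. Gene symbols and positions came from GENCODE release 29, in which 93.1% of the 60483 identifiers had a symbol. The authors' own annotation release is not given, so the match rests on the identifiers.

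Genes were kept with filterByExpr in edgeR 4.0.16 (R 4.3.3), grouped by treatment. This left 14412 genes, which held 99.9% of the counts. Counts were scaled by trimmed mean of M values (TMM) and tested with edgeR's quasi-likelihood F-test and Benjamini-Hochberg adjustment at 0.05. The model for pairs of treatments had treatment and time as additive terms, so that the 3 times stood in as replicates of a treatment and the spread was that of treatment by time. The interaction was the combination minus ibrutinib minus SPX5551 plus DMSO on the log2 scale. A model with time, ibrutinib exposure and SPX5551 exposure set the 6 ibrutinib-exposed libraries (ibrutinib and combination) against the other 6, and the 6 SPX5551-exposed libraries against the other 6. Adding time by ibrutinib exposure tested whether the ibrutinib effect differed between times. The common biological coefficient of variation was 0.101. Standard errors (SE) of edgeR were derived from the test, as the absolute log2 fold change divided by the square root of the F statistic. CPM values for single libraries carry a prior count of 2 only on the log2 scale.

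The lists of genes fixed before the data were examined covered the B-cell receptor early response, NF-kappaB targets, ribosome biogenesis and MYC targets, mitosis, DNA replication, FOXO targets and quiescence, the BCL2 family, sterol synthesis, amino acid and unfolded protein stress, interferon-stimulated genes, chemokine receptors with adhesion and migration, B-cell receptor signalling components, B-cell identity, plasma cell differentiation, p53 targets, hypoxia and glycolysis, mitochondrial transcripts, markers of T cells, of myeloid cells, and of stromal and epithelial cells, and the drug targets. The lists share a few members, such as CD22 (B-cell identity and B-cell receptor signalling components), BCL6 (B-cell identity and FOXO targets), XBP1 (stress and plasma cell lists) and ICAM1 (NF-kappaB targets and the adhesion list). The 18 lists with enough tested members were tested in 9 comparisons with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated per list. Of these 162 tests, 71 passed with the preset correlation and 6 with the estimated one. The list results described in detail were chosen after they were seen.

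Named genes followed a rule fixed in advance. In each main comparison these were, among genes with adjusted p under 0.05, a mean log2 CPM of at least 2 and the same sign of difference at 4, 8 and 12 h, the 10 with the largest positive and the 10 with the largest negative log2 fold change. Where fewer than 5 passed, the 5 with the smallest p were taken. List members with the smallest p served as examples of their list, and BTK, CXCR4 and CXCL12 were always named. Genes named outside this rule are marked as chosen after their values were seen.

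The procedure was tested on simulated counts with 200 genes changed among 14412. For ibrutinib versus DMSO, 58.2% of genes changed by 0.5 on the log2 scale and 98.5% of those changed by 1 were recovered. For SPX5551 versus DMSO these shares were 64.2% and 100%, for the combination versus DMSO 58.2% and 100%, and for the interaction 16.4% and 92.5%. For the ibrutinib-exposed comparison 94.0% were recovered at 0.5, and for the SPX5551-exposed comparison 97.0%.

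Alternatives fixed in advance were relative log expression factors, library size only, no filter on low counts, DESeq2 1.42.0, limma-voom, limma-trend on the deposited log2 CPM, the pairing in the descriptions, no time term, the 6 libraries of the groups compared, and leaving out each library or each time. Added after seeing the data were an offset that removes each library's trend on transcript length and GC content, leaving out the 8 h ibrutinib and 12 h SPX5551 libraries, and thinning all libraries to the smallest total. Transcript length and GC content were known for 99.3% of the tested genes. No sample and no column was left out of the comparisons.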

Results

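RNA sequencing libraries were made from REC1, an established human mantle cell lymphoma cell line, after exposure to DMSO, ibrutinib, SPX5551 or both agents together (the combination). Ibrutinib is a covalent inhibitor of BTK, the kinase that passes signals on from the B-cell receptor. SPX5551, named pol5551 in the headers of the deposited tables, is the agent that the study's title presents as an inhibitor of CXCR4, the receptor of the chemokine CXCL12. Each treatment was sampled at 4, 8 and 12 h with 1 library per treatment and time. The study asked how REC1 cells respond to CXCR4 inhibition, to a targeted agent and to both. At 4, 8 and 12 h, the libraries held 19927190, 20147758 and 19497655 counts for DMSO, 21548332, 28121563 and 19336303 for ibrutinib, 19888090, 26600088 and 20240842 for SPX5551, and 22951827, 28934030 and 24432822 for the combination. There was no replicate library within a treatment and time, so the 3 times served as the replicates of a treatment (n = 3). All p-values measure only the spread between these samples.

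The labels contradict each other on which column belongs to which sample. Sample titles and treatments match the column headers, while each sample's free-text description names the column of another treatment at the same time. By the descriptions, DMSO samples own the combination columns, ibrutinib samples the DMSO columns, SPX5551 samples the ibrutinib columns and combination samples the SPX5551 columns. The same shift holds at each time. It pairs the headers in alphabetical order (combo, dmso, ibr, pol5551) with samples in the order DMSO, ibrutinib, SPX5551 and combination. All values below follow the headers. Under the descriptions the ibrutinib and combination effects relative to DMSO change sign in all named genes that passed, whereas 2 of 31 such genes do so for the combination versus ibrutinib. As a check fixed in advance, 21 measured genes that respond early to B-cell receptor signals were compared between ibrutinib-exposed and unexposed libraries. Under the headers, their median log2 difference was -1.13 at 4 h, -0.47 at 8 h and -1.05 at 12 h, with 18 of 21 genes lower at each time. The descriptions exchange the exposed and unexposed columns, so the same medians with the opposite sign, 1.13, 0.47 and 1.05, follow from them by construction.

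The libraries differed along a trend with transcript length that did not follow treatment or time alone. The leading principal components held 33.7% and 19.1% of the variance. Spearman's rho between a gene's deviation from its mean over the libraries and its transcript length, computed across genes within a library, ranged from -0.55 in the 8 h SPX5551 library to 0.54 in the 8 h ibrutinib library. All 3 SPX5551 libraries had a negative rho and all 3 ibrutinib libraries a positive one. The 8 h ibrutinib library was closest to the 12 h DMSO library (r = 0.992 across genes), and the 12 h SPX5551 library was closest to the 8 h SPX5551 library (r = 0.992). Genes are not independent replicates.

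**Figure D1:**
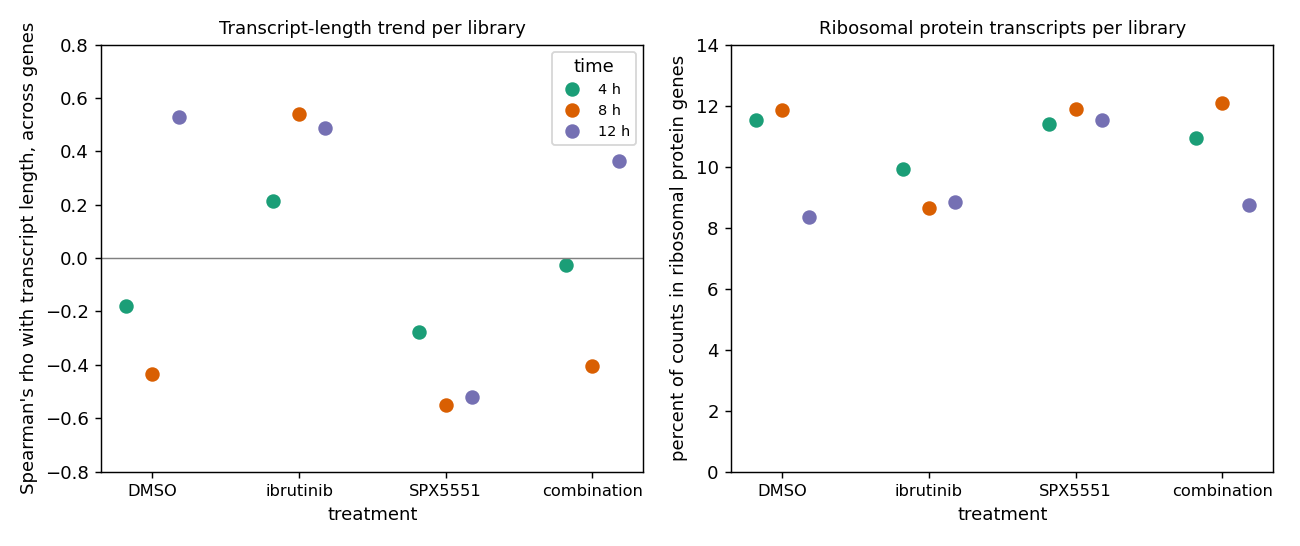
Left, Spearman's rho across genes between transcript length and each library's deviation from the mean of all libraries; right, percent of counts in ribosomal protein genes; 1 point per library, coloured by time. The 8 h ibrutinib library (rho 0.54, 8.65%) lies with most 12 h libraries, and the 12 h SPX5551 library (rho -0.52, 11.5%) lies with the other 8 h libraries.

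The transcripts of the drug targets themselves did not pass the test in any treatment comparison. BTK (chromosome X, 101349447 to 101390796, hg38) had 315, 307 and 376 CPM in DMSO at 4, 8 and 12 h, and 316, 333 and 356 CPM with ibrutinib. CXCR4 (chromosome 2, 136114349 to 136118165) had 17.9, 26.0 and 20.9 CPM in DMSO and 22.1, 26.7 and 20.95 CPM with SPX5551. The log2 fold change of CXCR4 for SPX5551 versus DMSO was 0.12 ± 0.13 (SE, n = 3; adjusted p = 0.790, edgeR), and that of BTK for ibrutinib versus DMSO was 0.02 ± 0.08 (adjusted p = 0.954). CXCL12 was listed at 0 counts in every library.

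The first question was what ibrutinib alone changed relative to DMSO. Some genes that respond early to B-cell receptor signals, cytokines among them, fell. TNF, an inflammatory cytokine and NF-kappaB target, fell by 2.28 ± 0.31 on the log2 scale (SE, n = 3; adjusted p = 0.00388, edgeR), from 14.3, 10.9 and 21.7 CPM at 4, 8 and 12 h in DMSO to 1.04, 4.196 and 4.45 CPM. The activation markers CD83 and CD69 fell by 1.42 ± 0.20 and 1.34 ± 0.17. DUSP2, a phosphatase that turns off MAP kinases, fell by 1.20 ± 0.14, and EGR3, an early growth response transcription factor, fell by 3.87 from 2.57, 1.02 and 2.72 CPM. In the same direction went NFKBID (-1.32) and NFKBIA (-1.06), both inhibitors of NF-kappaB and its targets, the cytokine LTA (-0.96), the NF-kappaB target TNFAIP2 (-0.82), the long non-coding RNA LINC01480 (-0.76) and CD180 (-0.70), a Toll-like receptor homologue of B cells.

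In all, 15 genes passed for ibrutinib versus DMSO (edgeR's quasi-likelihood test), 0 higher and 15 lower, with 1588 genes at an unadjusted p under 0.05. The chemokine CCL4 (-2.36) was among them, and the remaining 3, named after their values were seen, were the chemokines CCL3 (-2.15) and CCL3L3 (-3.37) and MIR17HG (-0.54), the host transcript of a microRNA cluster. CCL3 and CCL3L3 are near-identical copies, and how reads were divided between them, or with CCL4, is uncertain. The strand setting of the counting is not given, so reads from antisense or overlapping transcripts may be included. Of the 21 tested B-cell receptor early response genes, 7 fell and 14 did not pass (12 fell when adjusted over the list alone). The list's median log2 fold change was -0.61 (camera adjusted p = 8.0e-34; adjusted p = 0.0287 with an estimated correlation). Of 20 NF-kappaB targets, 3 fell (13 adjusted over the list alone), with a median of -0.54 (camera adjusted p = 2.8e-20; adjusted p = 0.0658 with an estimated correlation). Without the 4 h time point 0 genes of either list passed in edgeR, and without 8 h 6 NF-kappaB targets fell, and without 12 h 8 fell and 1 rose. The first list's median was -0.98 without 8 h. Its adjusted p with an estimated correlation was 0.346 without 4 h, 0.504 without 12 h and 0.0640 without the 8 h ibrutinib and 12 h SPX5551 libraries. TNFAIP3, an NF-kappaB inhibitor of that list, was at -0.70 and did not pass. None of 23 ribosome biogenesis and MYC target genes passed, also when adjusted over the list alone, and 3 fell without the 12 h time point. Their median was -0.18 (-0.12 with the length and GC trend removed), with 21 of 23 negative (camera adjusted p = 1.2e-05; adjusted p = 0.345 with an estimated correlation).

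DESeq2 called 40 genes for ibrutinib versus DMSO, and a fit with no filter on low counts 216; without a time term 0 passed, and without the 8 h ibrutinib and 12 h SPX5551 libraries 42 did. The count was 4 without the 4 h DMSO library, 6 without the 4 h ibrutinib library, 3 without the 12 h ibrutinib library, 29 without the 12 h SPX5551 library, 0 without the 4 h time point, 670 without the 12 h time point and 26 with the 6 libraries of both groups alone.

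**Figure D2:**
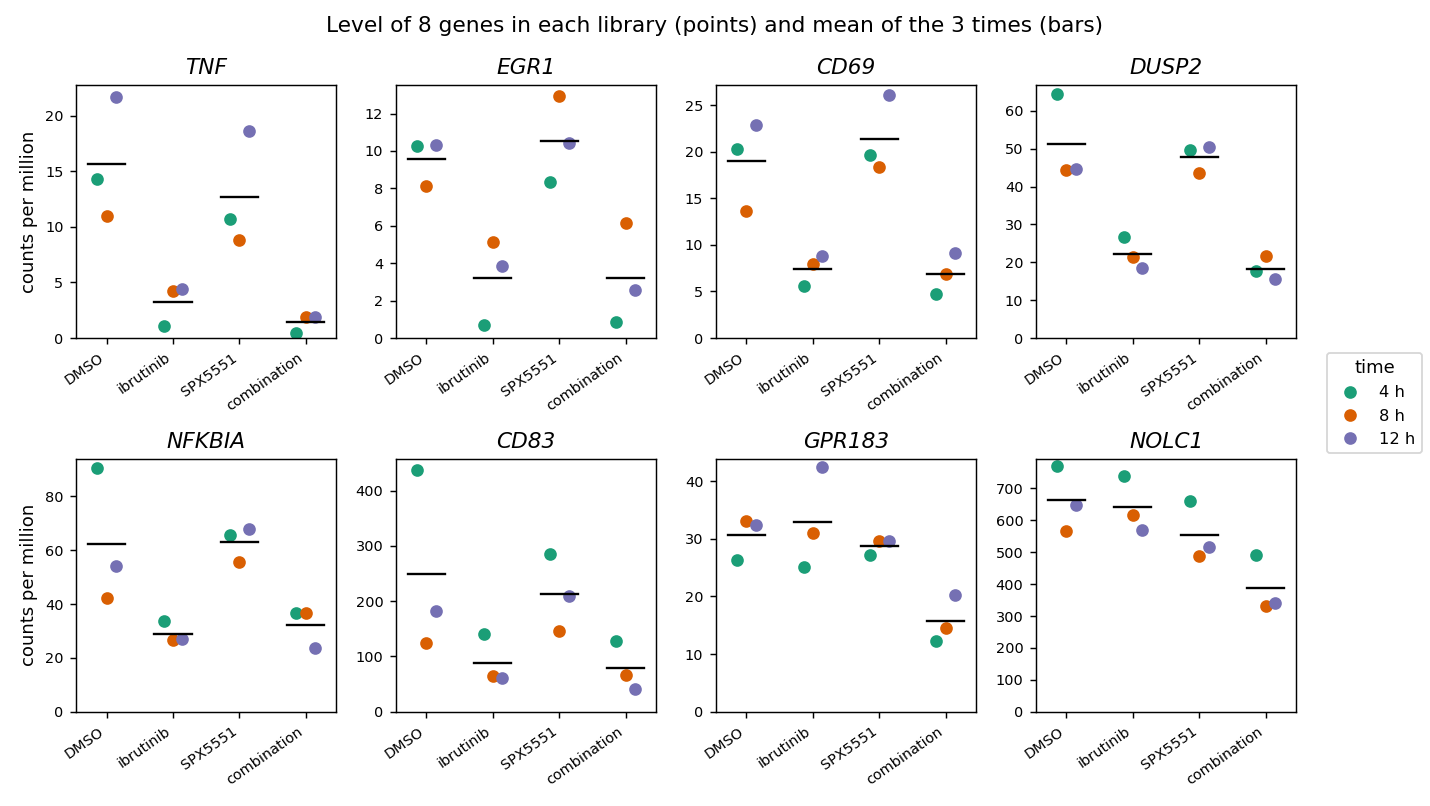
CPM (counts per 1e6 counts of the library) of 8 genes in each library (points, coloured by time; linear axes from 0) by treatment, with the mean of the 3 times as a bar. TNF, EGR1, CD69, DUSP2, NFKBIA and CD83 lie lower in the ibrutinib and combination libraries at each time, whereas GPR183 and NOLC1 are lowest in the combination.

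The next question was what CXCR4 inhibition alone changed. No gene passed for SPX5551 versus DMSO in edgeR (smallest adjusted p = 0.598), with 1200 genes at an unadjusted p under 0.05. DESeq2, limma-voom and limma-trend on the deposited log2 CPM also called 0, and the fit with no filter on low counts called 112. The 5 genes with the smallest p, none of which passed, were PLXNA1, a semaphorin co-receptor (log2 fold change -0.49 ± 0.11, SE, n = 3), the ribosomal pseudogene RPS27AP16 (1.07 ± 0.23), the motor protein MYO1E (-0.42 ± 0.10), the fatty acid synthase FASN (-0.55 ± 0.13) and GEMIN5, a component of the complex that assembles splicing particles (-0.44 ± 0.10). RPS27AP16 is a processed copy of a ribosomal gene and its reads may belong to another locus. It passed in the fit of the 6 DMSO and SPX5551 libraries alone (1 gene) and without the 4 h combination library (1 gene).

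Among the lists, genes of amino acid and unfolded protein stress had a median log2 fold change of 0.32 with SPX5551 (camera adjusted p = 2.5e-10; adjusted p = 0.502 with an estimated correlation). None of its 21 genes passed over all genes, and 3 were higher when adjusted over the list alone. Its members with the smallest p were the stress transcription factors ATF3 (1.01) and DDIT3 (0.43), the serine synthesis enzyme PHGDH (0.32) and the glutathione-degrading enzyme CHAC1 (0.90). Sterol synthesis had a median of -0.14 over 19 genes, none of which passed and 1 of which was lower when adjusted over the list alone (camera adjusted p = 2.2e-04; adjusted p = 0.825 with an estimated correlation). This median was -0.22 without the 4 h and -0.07 without the 12 h time point. Besides FASN, its members with a small p included the desaturase SCD (-0.33). All 3 SPX5551 libraries leaned to shorter transcripts, and log2 fold changes of SPX5551 versus DMSO followed length across genes with rho = -0.52.

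The combination versus DMSO gave 1379 genes against 15 for ibrutinib, and 785 against 670 without the 12 h time point. Under the pairing of the descriptions the counts were 1043 against 1379. These are the calls of the combination versus SPX5551 and versus DMSO with labels exchanged, so that order follows by construction. The list of ribosome biogenesis and MYC target genes held the most decreases. Of 23 genes, 20 fell and 3 did not pass (21 fell when adjusted over the list alone), with a median log2 fold change of -0.53 (camera adjusted p = 9.5e-26; adjusted p = 0.0499 with an estimated correlation). With the 4 or 8 h time point left out 9 or 12 fell, and the adjusted p with an estimated correlation was 0.0772 without the 8 h ibrutinib and 12 h SPX5551 libraries, 0.0495 with the length and GC trend removed, and 0.165 to 0.188 without single times. NOLC1, a nucleolar chaperone, fell by 0.78, NOP16 by 0.73, WDR43 by 0.68 and DKC1, the pseudouridine synthase dyskerin, by 0.65. MYC, named after its values were seen, fell by 1.06 ± 0.15 (adjusted p = 7.4e-04, edgeR), from 209, 213 and 221 CPM in DMSO at 4, 8 and 12 h to 64.9, 136 and 123 CPM.

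The B-cell receptor early response list also held many decreases with the combination. Of 21 genes, 11 fell, 1 rose and 9 did not pass (12 fell and 1 rose when adjusted over the list alone), with a median of -0.65 (camera adjusted p = 3.6e-18; adjusted p = 0.0499 with an estimated correlation). The latter p was 0.0818 with the trend removed, 0.135 without the 8 h ibrutinib and 12 h SPX5551 libraries, and 0.0655 to 0.215 without single times. The gene that rose, named after its values were seen, was FOSB (1.23), an AP-1 transcription factor. TNF fell by 3.46 ± 0.34, LTA by 1.56, CD83 by 1.60, CD69 by 1.46, DUSP2 by 1.46, CCL4 by 2.80, EGR3 by 3.23 and EGR1 by 1.76. Of 20 NF-kappaB targets, 10 fell (14 adjusted over the list alone), with a median of -0.48 (camera adjusted p = 2.3e-14; adjusted p = 0.0582 with an estimated correlation). Without the 4 h time point 4 fell. The 10 included the apoptosis inhibitor BIRC3 (-1.09), the adhesion molecule ICAM1 (-1.15) and TNFAIP2 (-0.88).

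Some receptors and adhesion molecules of migrating B cells fell with the combination as well. Of 21 tested genes, 9 fell, 1 rose and 11 did not pass (10 fell and 2 rose when adjusted over the list alone), with a median of -0.34 (camera adjusted p = 8.3e-06; adjusted p = 0.0499 with an estimated correlation). The latter p was 0.0899 with the trend removed, 0.135 without the 8 h ibrutinib and 12 h SPX5551 libraries, and 0.165 to 0.188 without single times; 4, 5 and 5 genes fell without 4, 8 and 12 h, and the median was -0.22 without 4 h. CXCR3, a chemokine receptor, fell by 1.91, GPR183, the oxysterol receptor that positions B cells in lymphoid follicles, by 0.98, and the hyaluronan receptor CD44 by 0.80. The gene that rose was GNAI2 (0.29), a G protein subunit of chemokine signalling, named after its values were seen. Of 19 sterol synthesis genes, 10 fell (12 adjusted over the list alone), with a median of -0.39 (camera adjusted p = 9.7e-10; adjusted p = 0.244 with an estimated correlation). Without the 8 h time point 1 fell, and without 12 h 5, with a median of -0.25. HMGCS1 fell by 0.89, INSIG1 by 0.65, SQLE by 0.62 and MSMO1 by 0.60; the first makes a precursor of mevalonate, INSIG1 restrains sterol-regulated transcription, and the last pair are later enzymes of the pathway. Of 13 B-cell identity genes, 2 fell (6 adjusted over the list alone), the transcription factors EBF1 (-0.42) and BCL6 (-0.57), with CD22 at -0.35 and PAX5 at -0.44 not passing (camera adjusted p = 0.00221; adjusted p = 0.244 with an estimated correlation); 0 passed in edgeR without 4 h or without 8 h.

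A few interferon-stimulated and FOXO-regulated genes rose. Of 18 interferon-stimulated genes, 3 rose and 15 did not pass (4 rose when adjusted over the list alone), with a median of 0.42 (camera adjusted p = 0.00404; adjusted p = 0.0582 with an estimated correlation). With each time point left out in turn, 1 gene of the list rose. The 3 were IFIT2 (1.70), which restrains viral translation, the transcription factor IRF7 (0.53) and the RNA sensor RIGI (0.47), whereas OAS1 was at 0.64 and did not pass. Of 16 FOXO target and quiescence genes, 4 rose, 2 fell and 10 did not pass (5 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.0381; adjusted p = 0.408 with an estimated correlation). Without 4 or 8 h 1 rose and 0 fell, and without 12 h 3 rose and 1 fell. YPEL3 rose by 1.06, the growth-restraining sestrins SESN3 and SESN1 by 0.73 and 0.49, and TXNIP, a negative regulator of glucose uptake, by 0.42. The largest increases by the naming rule included MXD4, a MYC antagonist (1.17 ± 0.17, SE, n = 3), ABTB1 (1.13 ± 0.15), YPEL3, EVI5L (1.04), SCAND1 (0.99), ULK1, a kinase that starts autophagy (0.99 ± 0.11), the transporter ABCA5 (0.95), CASP10, a caspase (0.95), and SAMD9L (0.91). The largest decreases also held HIVEP3, a zinc finger protein (-1.81 ± 0.23), the chemokine CXCL10 (-1.74), FJX1 (-1.61 ± 0.16) and the kinesin KIF26B (-1.48).

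In all, 1379 genes passed for the combination versus DMSO, 600 higher and 779 lower (edgeR's quasi-likelihood test). All 15 genes lower with ibrutinib alone were among the 779, where 0.811 would be shared by independent lists. Both comparisons used the same DMSO libraries and the same spread per gene, and part of the excess may come from these. With library size only as the scaling, the split was 1140 higher and 493 lower, while the median of all genes moved by less than 0.1. The count fell to 568 without the 8 h DMSO library, 586 without the 4 h and 698 without the 12 h DMSO library, and to 853, 767 and 773 without the 4, 8 and 12 h combination library; it was 278, 302 and 785 without the 4, 8 and 12 h time point, 27 with no time term, 2598 with the 6 libraries of both groups alone, 2302 with the length and GC trend removed, and 2549 without the 8 h ibrutinib and 12 h SPX5551 libraries.

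**Figure D3:**
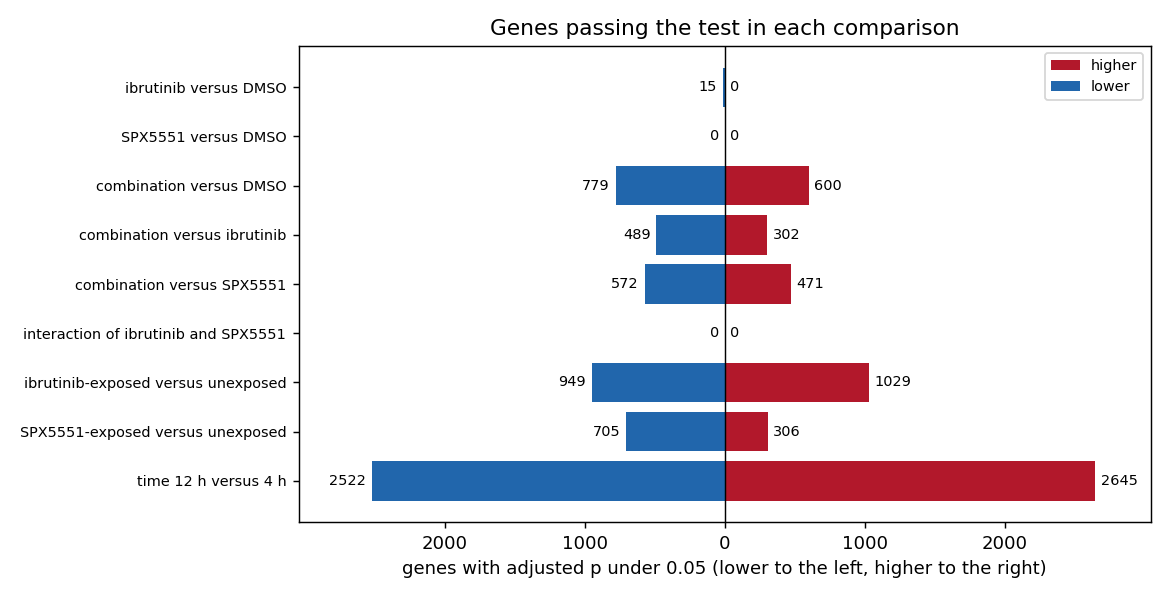
Number of genes with adjusted p under 0.05 in each comparison, lower genes to the left and higher genes to the right of 0. Ibrutinib versus DMSO had 15 genes and SPX5551 versus DMSO 0, against 1379 for the combination versus DMSO. Without the 12 h time point these were 670, 0 and 785. Under the pairing of the descriptions they were 1379, 791 and 1043, which are counts of other comparisons shown here with labels exchanged.

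The comparison of the combination with ibrutinib asked what SPX5551 added in the presence of ibrutinib. More ribosome biogenesis and MYC target genes fell. Of 23 genes, 9 fell (19 adjusted over the list alone), with a median of -0.30 (camera adjusted p = 1.3e-14; adjusted p = 0.189 with an estimated correlation), among them NOLC1 (-0.74), MYBBP1A (-0.58), WDR43 (-0.57) and the RNA polymerase I subunit POLR1B (-0.58). Of 19 sterol synthesis genes, 7 fell (11 adjusted over the list alone), with a median of -0.37 (camera adjusted p = 2.1e-08; adjusted p = 0.353 with an estimated correlation). SQLE fell by 0.61 and SCD by 0.65. Without the 12 h time point the median of this list was -0.23. Of 21 chemokine receptor, adhesion and migration genes, 5 fell (7 adjusted over the list alone), with a median of -0.27 (camera adjusted p = 8.9e-05; adjusted p = 0.189 with an estimated correlation), among them CD44 (-0.64), the integrin ITGA4 (-0.84), CXCR3 (-1.64) and GPR183 (-1.06 ± 0.12, SE, n = 3; adjusted p = 0.00163, edgeR). Without the 4 and 8 h time points 0 and 0 genes of the ribosome and MYC list passed, 1 and 0 of the sterol list and 0 and 0 of the migration list; with the trend removed 19 of the first fell.

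The other large decreases against ibrutinib were LRRC4 (-1.15 ± 0.20), FJX1 (-1.12 ± 0.16), HIVEP3 (-1.09), LHFPL2 (-1.07 ± 0.15), ELOVL6, a fatty acid elongase (-1.01), the complement receptor CR1 (-0.96), UNC13A (-0.93), the immunoglobulin joining pseudogene IGHJ3P (-0.92) and ADGRE2 (-0.92). The largest increases were ID1 (1.12 ± 0.27) and ID3 (0.94 ± 0.17), which block basic helix-loop-helix transcription factors, MZT2B (0.96), NRGN (0.95), DPM3 (0.94), ABTB1 (0.91), EGFL7 (0.86), ALKBH7 (0.85), SCAND1 (0.84) and CAPS (0.83). The combination and ibrutinib libraries also differed along the length trend: fold changes followed transcript length across genes with rho = -0.44.

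In all, 791 genes passed for the combination versus ibrutinib in edgeR, 302 higher and 489 lower, or 454 higher and 265 lower with library size only. DESeq2 called 1211, the fit with no filter 1404, the fit with no time term 0, and the fit with the length and GC trend removed 1251. The count was 84, 76 and 386 without the 4, 8 and 12 h ibrutinib library, 212 and 107 without the 4 and 8 h combination library, 526 without the 8 h DMSO library, 525 without the 8 h and 1244 without the 12 h SPX5551 library, and 2, 6 and 1643 without the 4, 8 and 12 h time point.

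The comparison of the combination with SPX5551 asked what ibrutinib added in the presence of SPX5551. Of 21 B-cell receptor early response genes, 11 fell (12 adjusted over the list alone), with a median of -0.67, among them CCL4 (-2.93), CCL3 (-2.50), CD69 (-1.63) and DUSP2 (-1.38). Of 20 NF-kappaB targets, 9 fell (15 fell and 2 rose when adjusted over the list alone), with a median of -0.47, among them TNF (-3.14), BIRC3 (-0.90), TNFAIP3 (-0.90) and TNFAIP2 (-0.82). Of 23 ribosome biogenesis and MYC target genes, 17 fell (20 adjusted over the list alone), with a median of -0.46, among them NOP16 (-0.68), ODC1 (-0.61), the rate-limiting enzyme of polyamine synthesis, DKC1 (-0.60) and NOLC1 (-0.53). Of 21 stress genes, 8 fell (13 adjusted over the list alone), with a median of -0.45, among them TRIB3 (-0.90), DDIT3 (-0.59), ATF3 (-1.23) and XBP1 (-0.47). Camera adjusted p was 1.7e-21, 2.8e-12, 5.5e-19 and 9.6e-11 for these 4 lists, and each had an adjusted p = 0.0828 with an estimated correlation. Without the 4, 8 and 12 h time points, 4, 11 and 8 of the ribosome and MYC list fell, 2, 5 and 4 of the stress list and 5, 10 and 6 NF-kappaB targets (1 rose without 12 h). The median of the B-cell receptor early response list was -1.004 without 8 h.

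In all, 1043 genes passed for the combination versus SPX5551 in edgeR, 471 higher and 572 lower, or 871 higher and 393 lower with library size only. All 15 genes lower with ibrutinib alone were among the 572, against 0.595 for independent lists. The comparison shares no library with ibrutinib versus DMSO, but both tests came from 1 model with the same spread per gene. The calls are therefore not independent, and 0.595 does not measure chance. The 8 h ibrutinib and 12 h SPX5551 libraries, which lay with the other time, each enter 1 of these comparisons. The count was 343 without the 8 h and 540 without the 12 h SPX5551 library, 514 without the 4 h and 395 without the 12 h combination library, and 129, 443 and 568 without the 4, 8 and 12 h time point. It was 5 with no time term, 496 with the 6 libraries of both groups alone, 1788 with no filter on low counts and 1800 with the length and GC trend removed.

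**Figure D4:**
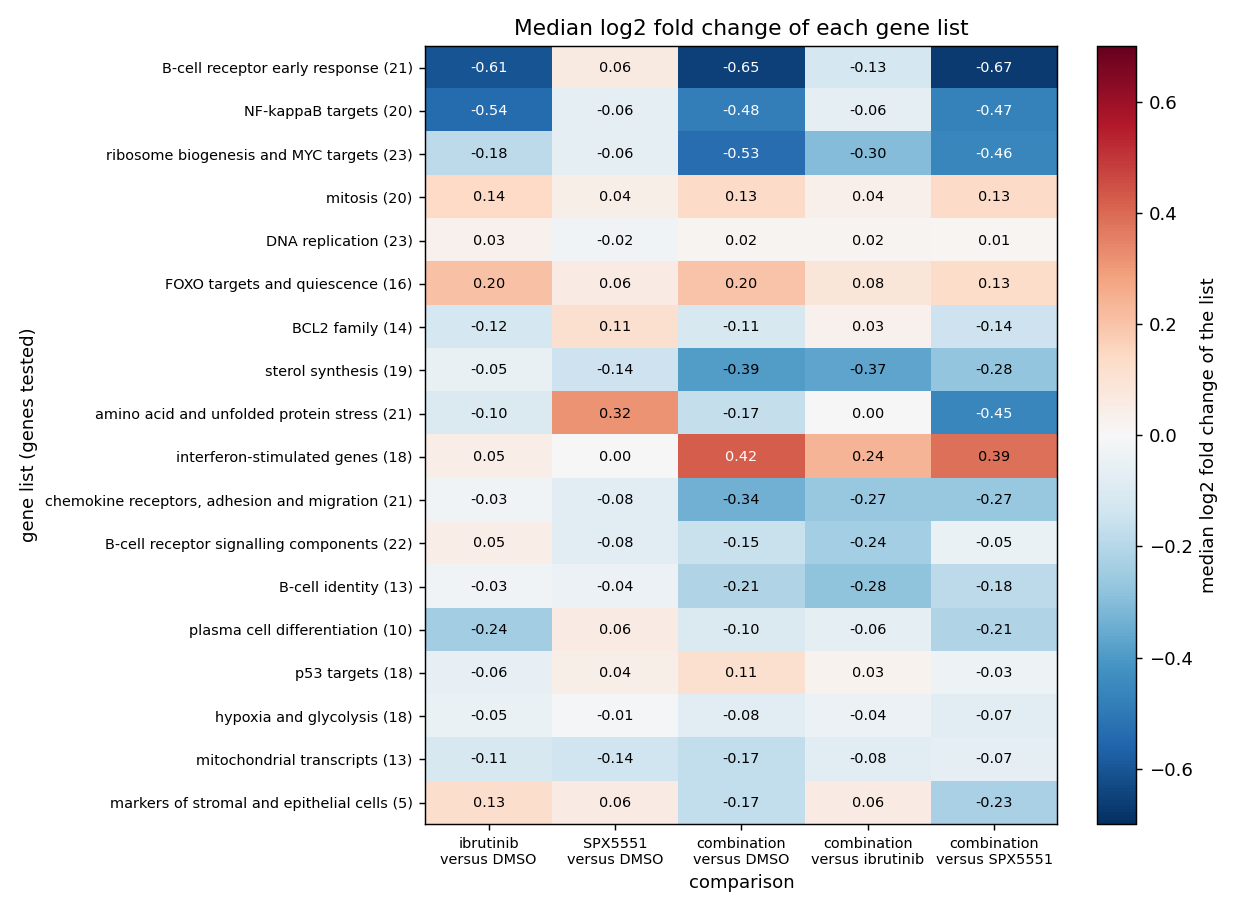
Median log2 fold change of each gene list (vertical, with the number of genes tested) in 5 comparisons (horizontal); blue is lower and red is higher. The B-cell receptor early response list reads -0.61 for ibrutinib versus DMSO and 0.06 for SPX5551 versus DMSO, and ribosome biogenesis and MYC targets reads -0.53 for the combination versus DMSO.

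The effect of ibrutinib across genes was compared with and without SPX5551. Over 10113 genes, log2 fold changes of ibrutinib versus DMSO and of the combination versus SPX5551, which share no library, correlated at r = 0.670 (Spearman's rho 0.662), with the same sign in 75.9% of genes. With the length and GC trend removed r was 0.648, and without the 12 h time point 0.299. At single times r was 0.325, 0.144 and 0.248 at 4, 8 and 12 h. For SPX5551 versus DMSO and the combination versus ibrutinib, r was 0.603, and 0.543 with the trend removed. In each pair, 1 of the 8 h ibrutinib and 12 h SPX5551 libraries enters each difference. Both lay with libraries of the other time and shift both differences the same way, so part of each r may come from them. The r with only these libraries left out was not computed. These correlations are across genes, which are not independent replicates.

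Pairs that share the DMSO libraries were set against simulated groups with no effect. The simulated counts held no transcript-length trend, so a gap between real and simulated values cannot be read as a shared effect of the agents. For ibrutinib and the combination, r was 0.454 against a simulated 0.510, and the covariance was 0.0214 against 0.00871. For SPX5551 and the combination, r was 0.310 against 0.507, and the covariance was 0.0126 against 0.00867. For ibrutinib and SPX5551, r was -0.350 against 0.506, and the covariance was -0.0102 against 0.00871. With the trend removed from the real values, r was 0.551 for ibrutinib and the combination, 0.395 for SPX5551 and the combination, and -0.10 for ibrutinib and SPX5551.

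Whether both agents together did more than the sum of their log2 effects was tested as an interaction. No gene passed in edgeR (smallest adjusted p = 0.285), with 845 at an unadjusted p under 0.05. Limma-voom and the deposited log2 CPM gave 0, DESeq2 gave 2 and the fit with no filter 32. The pair called by DESeq2, named after their values were seen, were GPR183 (-0.99; adjusted p = 0.00664) and PALD1 (-0.87; adjusted p = 0.00776). Of 23 ribosome biogenesis and MYC target genes, 22 had a negative interaction, with a median of -0.28 (camera adjusted p = 7.0e-12; adjusted p = 0.240 with an estimated correlation). Without the 12 h time point this median was -0.09 (camera adjusted p = 0.00990). None passed over all genes, and 2 did when adjusted over the list alone. The smallest p belonged to NOLC1, DKC1, NCL and PA2G4. Leaving out the 12 h time point gave 109 genes, leaving out the 8 h ibrutinib library or the 8 h time point 1, removing the trend 1, and leaving out the 8 h ibrutinib and 12 h SPX5551 libraries 8.

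Pooling the 6 ibrutinib-exposed libraries against the other 6 averaged the effect of ibrutinib without and with SPX5551, in a model with no interaction term. The exposed side held the 8 h ibrutinib library and the other side the 12 h SPX5551 library, both of which lay with the other time. TNF fell by 2.67 ± 0.24 (SE, n = 6; adjusted p = 4.3e-06, edgeR), EGR1 by 1.78 ± 0.27, CD69 by 1.49 ± 0.12, CD83 by 1.48 ± 0.13, DUSP2 by 1.29 ± 0.10, NFKBID by 1.27, CXCL10 by 1.25, LTA by 1.17, KIF26B by 1.04 and NFKBIA by 1.02. Of 21 B-cell receptor early response genes, 13 fell (15 adjusted over the list alone), CCL4 (-2.64) and EGR3 (-3.32) among them, with a median of -0.64 (camera adjusted p = 4.9e-33; adjusted p = 0.0160 with an estimated correlation). Of 20 NF-kappaB targets, 13 fell (14 fell and 1 rose when adjusted over the list alone), TNFAIP2 by 0.82 and BIRC3 by 0.71 among them, with a median of -0.50 (camera adjusted p = 2.0e-19; adjusted p = 0.0413 with an estimated correlation). Without the 12 h time point 7 of these fell. With an estimated correlation the adjusted p of both lists was 0.156 without 4 h and 0.0137 without 8 h, it was 0.121 and 0.181 without 12 h, and 0.0382 and 0.0502 without the 8 h ibrutinib and 12 h SPX5551 libraries.

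Of 23 ribosome biogenesis and MYC target genes, 17 fell with ibrutinib exposure (18 adjusted over the list alone), including NOP16 (-0.53), NME1 (-0.52), ODC1 (-0.44) and NOP56 (-0.36). The list's median was -0.32 (camera adjusted p = 5.2e-14, or 0.179 with an estimated correlation). Without the 4, 8 and 12 h time points 11, 0 and 4 fell. Versus DMSO, 0 of the 23 passed for ibrutinib alone (median -0.18) and 20 fell with the combination (median -0.53). Of 21 stress genes, 7 fell (12 adjusted over the list alone; median -0.27; camera adjusted p = 9.1e-08; adjusted p = 0.179 with an estimated correlation), including DDIT3 (-0.48), TRIB3 (-0.67), SDF2L1 (-0.49) and HERPUD1 (-0.35); 3, 1 and 2 fell without the 4, 8 and 12 h time points. Of 20 mitosis genes, 9 rose, the same number as when adjusted over the list alone (median 0.12; camera adjusted p = 0.00478; adjusted p = 0.179 with an estimated correlation), including the kinesin KIF20A (0.30), CENPE (0.41), MKI67 (0.47) and TOP2A (0.28). With the length and GC trend removed 10 of them rose, and without the 8 h ibrutinib and 12 h SPX5551 libraries 0 did; without the 4, 8 and 12 h time points 2, 0 and 0 did. The largest increases were ZBED6 (0.82), RAVER1 (0.78 ± 0.11), SAMD9L (0.73), AAK1 (0.72 ± 0.12), RAPGEF2 (0.71), the cytoskeletal linker PLEC (0.66 ± 0.09), PGM2L1 (0.66), YPEL3 (0.66), AHNAK (0.66) and SAMD9 (0.64).

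In all, 1978 genes passed for ibrutinib exposure in edgeR, 1029 higher and 949 lower; the split was 1642 and 605 with library size only and 742 and 1115 with the deposited log2 CPM. Exposure went with the length trend: rho between transcript length and the library's deviation was positive in 4 of the 6 exposed and 1 of the 6 unexposed libraries, and fold changes followed length across genes with rho = 0.48. With the trend removed, 2034 genes passed, of which 1255 were among the 1978 in the same direction. Of the 1978, 449 were also called higher and 438 also called lower for 12 h versus 4 h. Independent lists would share 189 and 166, but both tests used all 12 libraries, so these lists are not independent. The count was 1051 and 881 without the 4 and 8 h DMSO library, 965 without the 8 h ibrutinib library, 748 and 515 without the 8 and 12 h SPX5551 library, and 750 and 408 without the 4 and 12 h combination library. It was 671, 83 and 182 without the 4, 8 and 12 h time point, 29 with no time term, and 512 without the 8 h ibrutinib and 12 h SPX5551 libraries.

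The 6 SPX5551-exposed libraries were likewise set against the other 6. MYO1E fell by 0.66 ± 0.09 (SE, n = 6; adjusted p = 0.00933, edgeR), HIVEP3 by 0.85 ± 0.16, LRRC4 by 0.79, LHFPL2 by 0.73, the NF-kappaB subunit REL by 0.73, CTTNBP2 by 0.73 ± 0.11, the ribosome assembly ATPase MDN1 by 0.70, the pseudogene IGHJ3P by 0.69, SPEN by 0.67 and PPARGC1B, a coactivator of mitochondrial genes, by 0.66. RPS27AP16 (0.82), ID1 (0.77), ABTB1 (0.68), DHRS2 (0.67), ID3 (0.59), WIPI1, an autophagy protein (0.58 ± 0.10), MXD4 (0.57), DPM3 (0.56), CAPS (0.52) and TRAPPC2B (0.52) rose. Of 23 ribosome biogenesis and MYC target genes, 7 fell (13 adjusted over the list alone; median -0.20; camera adjusted p = 6.6e-09; adjusted p = 0.476 with an estimated correlation), including MYBBP1A (-0.44), NOLC1 (-0.50), WDR43 (-0.42) and POLR1B (-0.42). Of 19 sterol synthesis genes, 7 fell (11 adjusted over the list alone; median -0.23; camera adjusted p = 3.9e-08; adjusted p = 0.476 with an estimated correlation), including FASN (-0.47) and SCD (-0.49). Without the 8 or 12 h time point 0 genes of either list passed in edgeR, and the sterol median was -0.13 without 12 h. With the trend removed 17 of the first list fell, and without the 8 h ibrutinib and 12 h SPX5551 libraries 12 of the first and 3 of the second did.

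In all, 1011 genes passed for SPX5551 exposure in edgeR, 306 higher and 705 lower, or 433 higher and 315 lower with library size only. Fold changes followed transcript length across genes with rho = -0.52, and 661 of the 1011 genes passed in the same direction with the length and GC trend removed. DESeq2 called 1534 and the fit with no filter 1658. The count was 142 without the 12 h DMSO library, 244, 127 and 532 without the 4, 8 and 12 h ibrutinib library, 1807 and 460 without the 4 and 12 h SPX5551 library, 331, 81 and 605 without the 4, 8 and 12 h combination library, 637, 0 and 0 without the 4, 8 and 12 h time point, 0 with no time term, and 257 without the 8 h ibrutinib and 12 h SPX5551 libraries.

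Whether the ibrutinib effect differed between 4, 8 and 12 h was tested on 2 exposed and 2 unexposed libraries per time. No gene passed in edgeR (smallest adjusted p = 0.607), with 252 at an unadjusted p under 0.05. Limma-voom and the deposited log2 CPM gave 0, DESeq2 gave 2 and the fit with no filter 21. The pair called by DESeq2, named after their values were seen, were EGR1 and TNF. EGR1 was lower in exposed libraries by -3.41 at 4 h, -0.86 at 8 h and -1.70 at 12 h on the log2 scale, and TNF by -4.01, -1.77 and -2.74.

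The comparison of 12 h with 4 h called the most genes. A difference in library preparation between the times cannot be told apart from time here. Of 13 B-cell identity genes, 8 rose between 4 and 12 h, over all genes and when adjusted over the list alone, with a median of 0.44 (camera adjusted p = 2.3e-05; adjusted p = 0.326 with an estimated correlation). CIITA, which drives antigen presentation genes, rose by 1.12, POU2AF1 by 0.97, IRF8 by 0.63 and CD22 by 0.62. Of 23 ribosome biogenesis and MYC target genes, 15 fell (17 adjusted over the list alone; median -0.38; camera adjusted p = 1.2e-07; adjusted p = 0.326 with an estimated correlation), including ODC1 (-0.71), NOP16 (-0.67), LDHA (-0.66) and DKC1 (-0.57). Of 18 hypoxia and glycolysis genes, 7 fell, over all genes and adjusted over the list alone (median -0.23, or -0.15 with library size only; camera adjusted p = 0.00242; adjusted p = 0.326 with an estimated correlation), including CA9, a carbonic anhydrase (-3.16), BNIP3 (-0.96), PGK1 (-0.64) and ENO1 (-0.61). In all, 5167 genes passed for 12 h versus 4 h in edgeR (4 libraries per time), 2645 higher and 2522 lower. With library size only, 3524 were higher and 1676 lower. Fold changes of this comparison followed transcript length across genes with rho = 0.22.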

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

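The tests of the length and GC trend and of a more than additive effect, and the bound for the pairing of columns, were chosen after results were seen, as were 3 alternatives: the trend removal, the omission of the 8 h ibrutinib and 12 h SPX5551 libraries, and the thinning of libraries. The splits balanced over times were added after the other splits were seen.

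Some libraries lay far from the others of their time. At 8 h the ibrutinib library had 8.65% of its counts in ribosomal protein genes, against 11.9 to 12.1% in the other 3, and a length rho of 0.54, against -0.55 to -0.41. At 12 h the SPX5551 library had 11.5%, against 8.36 to 8.85%, and a length rho of -0.52, against 0.36 to 0.53. Among the 6 libraries without ibrutinib, the 12 h DMSO library had the lowest ribosomal protein percent (8.36, against 11.4 to 11.9 in the other 5) and the highest length rho (0.53), and the 8 h SPX5551 library had the largest total, 26.6 in units of 1e6 counts (19.5 to 20.2 in the others). BTK stood at 272.8 CPM in the 4 h combination library, against 314.7 to 320.5 CPM in the other 4 h libraries. In all, 8 of 40 sets of libraries held such a value, where chance gives about 1 in 20 for independent sets. These sets share libraries, and the length rho and ribosomal protein percent flagged the same ones. The count therefore cannot be set against that share.

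For 6 of 122 named genes, an agent's effect had one sign at each of the 3 times without the other agent and the opposite sign at each time with it. With ibrutinib, the mean log2 effects without and with SPX5551 were -0.37 and 0.60 for NRGN (difference 0.97), -0.28 and 0.80 for EGFL7 (difference 1.08), 0.32 and -0.38 for ADGRE2 (difference -0.70), and 0.10 and -0.28 for IRF8 (difference -0.38). With SPX5551, the effects without and with ibrutinib were -0.25 and 0.22 for AAK1 (difference 0.47), and 0.12 and -0.26 for XBP1 (difference -0.38). Independent random signs would give 7.62 such cases over both agents. Many of the 122 genes were named for the same sign of difference at all 3 times, so this value does not measure chance here. None of the 6 passed the interaction test (adjusted p from 0.670 to 0.833, edgeR).

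The first pattern was the lower B-cell receptor early response in libraries whose headers name ibrutinib. Under the descriptions these genes would instead be higher with ibrutinib, with a lowest median over the 3 times of 0.47. Both readings come from the same difference with its sign turned, because the descriptions exchange the exposed and unexposed columns. The pairings therefore cannot be told apart by these values without assuming the direction of the ibrutinib effect, and no value used here settles that. A response to BTK inhibition was not tested separately from the pairing.

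The second pattern was the larger number of genes versus DMSO with the combination (1379; 3539 at an unadjusted p under 0.05) than with ibrutinib (15; 1588) or SPX5551 (0 in edgeR, limma-voom and DESeq2; 1200). Without the 12 h time point the counts were 785, 670 and 0. Under the pairing of the descriptions, which stays open, they were 1043, 1379 and 791. The latter are counts of other comparisons with labels exchanged, and do not test the ranking. The combination ranked first only under the headers, and narrowly without 12 h. Under the headers, larger combination libraries were argued against by thinning every library to the smallest total, which left 1328 genes. Removing the length and GC trend left 2302 genes, 1300 of them among the 1379 in the same direction. This cannot decide on the trend, since fold changes of the combination versus DMSO hardly followed length (rho = 0.01 across genes). Those of ibrutinib (rho = 0.58) and SPX5551 (rho = -0.52) versus DMSO did. Whether the effects of the 2 agents were more than additive cannot be told apart from a sum of smaller effects. In the interaction test 0 genes passed in edgeR (845 at an unadjusted p under 0.05; DESeq2 2), and on simulated counts that test recovered 16.4% of genes with an interaction of 0.5 and 92.5% at 1.

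The third pattern was the length-dependent difference between libraries. Whether it was the whole cause of the ibrutinib calls was not decided. Of the 1978 genes, 1255 (63.4%) were called again in the same direction with the trend removed. This share lay between the bounds set for and against that cause, the latter being 2 in 3. For the 723 genes not called again, the median absolute log2 fold change went from 0.29 to 0.15 (52.9% of its value) and the median SE from 0.08 to 0.06; these calls ended because the fold changes shrank, between the bounds set, so the trend as their cause stays open. An exchange of time labels between the 8 h ibrutinib and 12 h SPX5551 libraries was also examined. On 500 genes that separate 8 h from 12 h in the other libraries, with the trend removed, they scored 0.13 and -0.17. The other 8 h libraries lay at -0.37 to -0.34 and the other 12 h libraries at 0.32 to 0.40. Both scored on the side of the other time, as the exchange predicts. A difference in library preparation along the same split would give this too. The genes were chosen with ibrutinib alone only among the 12 h libraries and SPX5551 alone only among the 8 h libraries. A treatment difference could therefore move both scores the same way. At 4 h, ibrutinib scored -0.17, the combination -0.25, SPX5551 -0.29 and DMSO -0.35. The ranges of the other libraries come from those that the genes were chosen to separate. An exchange of times alone would, however, leave 2 ibrutinib libraries of 12 h and 2 SPX5551 libraries of 8 h. The design has 1 library per treatment and time, so the cause of these scores is not settled.

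Other splits of the same libraries were counted for each comparison. With 3 libraries against 3 there are only 10 splits, too few for a share under 0.05. The real split gave 15 genes for ibrutinib versus DMSO (1 of 10 splits as large; highest other 0), 0 for SPX5551 versus DMSO (10 of 10; highest other 0), 1379 for the combination versus DMSO (1 of 10; 0), 791 versus ibrutinib (1 of 10; 0) and 1043 versus SPX5551 (1 of 10; 95). For 12 h versus 4 h, 1 of 35 splits gave as many as the real 5167 (highest other 0), a share under 0.05. Most of these splits do not keep 1 library of each treatment on either side, as the real one does. Splits that do were not counted separately, so chance is not excluded among them. For ibrutinib exposure, 2 of 100 splits gave at least 1978, the real one included. The highest other, 2485, kept 5 of the 6 exposed libraries, with the 4 h SPX5551 in place of the 12 h ibrutinib library. For SPX5551 exposure, 3 of 100 gave at least 1011. The highest other, 3198, set the 3 combination, the 12 h SPX5551 and the 4 and 12 h ibrutinib libraries against the rest, and points to a structure of the samples beyond SPX5551 exposure. Most of these splits do not keep 2 libraries of each time on either side, as the real ones do. Among splits that do, 100 of the 108 possible drawn for each, 1 gave at least 1978 for ibrutinib exposure (highest other 308). For SPX5551 exposure 1 gave at least 1011 (highest other 231), in both cases the real one. This argues against chance among such splits, although other splits leave the exposure effect in the spread, which lowers their counts. Both real splits also set the 8 h ibrutinib against the 12 h SPX5551 library, so these shares cannot separate exposure from that difference. For the interaction the real count was 0, so 100 of 100 splits gave at least as many by definition, which says nothing about chance; the highest other, 2191, points to a structure of the samples.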

How the results depend on the processing

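The removal of the length and GC trend, the omission of the 8 h ibrutinib and 12 h SPX5551 libraries and thinning were chosen after seeing the data. The counts below are of genes with adjusted p under 0.05. Relative log expression factors, library size only, limma-voom, the deposited log2 CPM and thinning kept each count of a comparison within 1.5 times the reported one. Of the named genes that passed, none changed sign, excluding the pairing of the descriptions. In every alternative, 0 of 12 passed for ibrutinib versus DMSO, 7 of 44 for the combination versus DMSO, 0 of 31 versus ibrutinib and 1 of 16 versus SPX5551. For ibrutinib exposure 9 of 36 did, for SPX5551 exposure 0 of 28 and for time 12 of 12. Where the share was 0, the fit with no time term called 0 genes, so no gene could pass in every alternative. In at least 1 in 2 of the alternatives, these numbers were 11, 44, 30, 16, 35, 24 and 12, in the same order. The medians of 31 list results kept their sign under 3 scalings, though not always their size: with library size only, B-cell identity for the combination versus DMSO went from -0.21 to -0.13 and hypoxia and glycolysis for time from -0.23 to -0.15. For single genes and lists, 4946 alternative values were the same, 50 newly passed, 690 no longer passed, 21 reversed and 25 moved. Except where named, the cause was not tested.

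With no filter on low counts, 216 genes passed for ibrutinib versus DMSO, 112 for SPX5551 versus DMSO, 1404 for the combination versus ibrutinib, 1788 versus SPX5551, 32 for the interaction, 1658 for SPX5551 exposure and 21 for ibrutinib by time. DESeq2 gave 40, 1211 for the combination versus ibrutinib, 2 for the interaction, 1534 for SPX5551 exposure and 2 for ibrutinib by time. With no time term, 0 passed for ibrutinib versus DMSO, 27 for the combination versus DMSO, 0 versus ibrutinib, 5 versus SPX5551, 29 for ibrutinib exposure and 0 for SPX5551 exposure; the time differences then entered the spread. With the 6 libraries of both groups alone, the counts were 26 for ibrutinib, 1 for SPX5551 and 2598 for the combination versus DMSO, and 496 for the combination versus SPX5551. With the trend removed, they were 2302 for the combination versus DMSO, 1251 versus ibrutinib, 1800 versus SPX5551 and 1 for the interaction. Without the 8 h ibrutinib and 12 h SPX5551 libraries, they were 42 for ibrutinib and 2549 for the combination versus DMSO, 8 for the interaction, 512 for ibrutinib exposure, 257 for SPX5551 exposure and 1 for ibrutinib by time. Of the 71 list calls, 6 held with an estimated correlation.

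The pairing of the descriptions exchanges the groups by construction. Across genes, its log2 fold changes had a negative correlation with the reported ones for ibrutinib (r = -0.503), SPX5551 (-0.358) and the combination (-0.733) versus DMSO, the combination versus SPX5551 (-0.601), ibrutinib exposure (-0.9997) and SPX5551 exposure (-0.321), but not for the combination versus ibrutinib (0.358; ribosome and MYC list -0.06, sterol -0.14, chemokine receptors -0.08) or the interaction (0.245; ribosome and MYC list -0.41, 9 genes lower). It gave 1379 genes for ibrutinib versus DMSO, 791 for SPX5551 versus DMSO, 1043 for the combination versus DMSO, 0 versus ibrutinib, 1896 versus SPX5551, 973 for the interaction, 378 for ibrutinib exposure and 0 for SPX5551 exposure. The pooled median of the direction check was 0.65. List medians became 0.65 (B-cell receptor early response), 0.48 (NF-kappaB) and 0.53 (ribosome biogenesis) for ibrutinib versus DMSO, and 0.37 (sterol synthesis) for SPX5551 versus DMSO. For the combination versus DMSO they were 0.46 (ribosome), 0.67 (B-cell receptor), 0.47 (NF-kappaB), 0.27 (chemokine receptors), 0.28 (sterol), -0.39 (interferon) and 0.18 (B-cell identity), and versus SPX5551 0.74 (B-cell receptor), 0.54 (NF-kappaB) and 0.40 (stress). For ibrutinib exposure they were 0.65, 0.50, 0.32 (ribosome), 0.27 (stress) and -0.12 (mitosis), and for SPX5551 exposure 0.14 (ribosome) and 0.11 (sterol).

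Leaving out single libraries or times gave 0 to 670 genes for ibrutinib and 0 to 1 for SPX5551 versus DMSO, 278 to 1671 for the combination versus DMSO, 2 to 1643 versus ibrutinib, 129 to 1302 versus SPX5551, 0 to 109 for the interaction, 83 to 2637 for ibrutinib exposure, 0 to 1807 for SPX5551 exposure, 0 to 1 for ibrutinib by time and 3517 to 5510 for time. The correlation of ibrutinib effects across genes with and without SPX5551 ran from 0.299 (without the 12 h time point) to 0.693 (without 4 h). Thinning to the smallest total (19336303 counts) changed no count by over 1.5 times, so none of them rested on the larger totals alone.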

Other observations

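With the combination versus DMSO, of 20 mitosis genes, 2 rose (4 adjusted over the list alone; camera adjusted p = 0.00840; adjusted p = 0.244 with an estimated correlation). Of 23 DNA replication genes, 1 rose (1 adjusted over the list alone; camera adjusted p = 0.427). Of 10 plasma cell differentiation genes, 3 fell (3 adjusted over the list alone; camera adjusted p = 0.0177; adjusted p = 0.127 with an estimated correlation). Of 18 hypoxia and glycolysis genes, 1 rose and 4 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.0381; adjusted p = 0.244 with an estimated correlation). Of 21 stress genes, 3 fell (4 adjusted over the list alone; camera adjusted p = 0.0314; adjusted p = 0.424 with an estimated correlation).

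Of 22 B-cell receptor signalling components, 1 fell with the combination versus DMSO (3 adjusted over the list alone; camera adjusted p = 0.00663; adjusted p = 0.349 with an estimated correlation), and 2 fell versus ibrutinib (10 adjusted over the list alone; camera adjusted p = 4.3e-04; adjusted p = 0.353 with an estimated correlation). Of 18 p53 targets, 1 rose and 2 fell versus DMSO (3 and 2 adjusted over the list alone; camera adjusted p = 0.573), and of 14 BCL2 family genes 1 rose and 1 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.187). Of 13 mitochondrial transcripts, 0 passed in edgeR over all genes or over the list alone, and all 13 had a negative log2 fold change (camera adjusted p = 0.0381; adjusted p = 0.513 with an estimated correlation). Of 5 tested markers of stromal and epithelial cells, 1 fell (CDH1, -1.06; 1 adjusted over the list alone; camera adjusted p = 0.267). Among markers of T cells, CD3D, CD3E and TRAC were tested, and TRAC fell by 1.72 (adjusted p = 0.0140, edgeR); among markers of myeloid cells, CD14 and ITGAM were tested.

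The tests of GPR183 below were chosen after its values were seen. GPR183 (chromosome 13, 99294530 to 99307405) had 26.4, 33.1 and 32.5 CPM in DMSO at 4, 8 and 12 h, 25.2, 30.9 and 42.4 with ibrutinib, 27.2, 29.6 and 29.6 with SPX5551, and 12.3, 14.5 and 20.3 with the combination. It was lower in the combination than in every other treatment at each time. Its interaction was -0.98 in edgeR (adjusted p = 0.285), -0.99 in DESeq2 (adjusted p = 0.00664) and -1.13 without the 8 h ibrutinib and 12 h SPX5551 libraries (8 genes; adjusted p = 0.00343). Whether both agents together lowered GPR183 by more than the sum of their effects is not settled by these values, since the edgeR test did not pass.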
